A study of Mus musculus with 20 samples.

How the data were processed

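MicroRNAs (miRNAs, short RNAs that lower the output of their target messenger RNAs) were measured in the ascending aorta, with its atherosclerotic lesion, of male double-knockout mice. The labels give the genotype as Apobtm2Sgy/Ldltm1Her. Each of 20 samples was hybridised to its own Agilent mouse miRNA array in 1 colour (Cy3), from total RNA taken with TRIZOL per the labels' protocols. The labels place 2 arrays at week 0 on chow and 3 arrays in each of 6 further groups, chow or high fat diet at weeks 6, 18 and 30. The series' design text writes its times in a way that splits the week 18 time into separate numbers, and the treatment protocol's 0, 6, 18 and 30 weeks were used. Replicates are separate samples by label only, so the p-values measure the spread between these samples, which can be technical in part.

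The deposited values are spot intensities on a linear scale from Agilent Feature Extraction 11.5.1, per the submitters' processing notes and the file headers. Per the file headers, pixel outliers were rejected, the background was subtracted and spatial trends were removed, with no scaling between arrays. The deposited value table held the same processed intensity in all 20 columns, and 0 of its columns were left unmatched. Each array has 58594 features, of which 56430 are mouse miRNA spots from 4415 probes for 1881 mature miRNAs and 2164 are control spots. Probe positions in the files refer to the mouse build mm9 (NCBI37). Each miRNA gene was looked up by name in a RefSeq gene table of assembly GRCm38.p6. Genes whose span in that assembly holds it were then taken by position, on either strand. No coordinate of that assembly is printed here.

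Control spots and spots marked as outliers (1422 to 2287 per array) were left out, and 0 spots were saturated. Spots were averaged per probe and probes per miRNA. A miRNA counted as detected on an array where at least 0.5 of the usable spots of 1 of its probes were well above background. Each array was divided by its 75th percentile over the 192 miRNAs detected on all 20 arrays, a common floor of 3.09 on the log2 scale was set, and log2 was taken. Values at the floor have no order and add no spread, which can make a standard error too small for a miRNA that lies at the floor in most groups. The test covered the 609 miRNAs detected on every array of at least 1 group. Where a miRNA has several probes, the lowest correlation between them over the arrays was below 0.5 for 22 of 589 miRNAs, with a median of 0.98. Close relatives, such as let-7 or miR-181 family members, can hybridise to one another's probes.

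Comparisons used limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 20 arrays and 7 groups with 13 residual degrees of freedom, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. The comparisons were the diet effect (high fat minus chow) at weeks 6, 18 and 30, its mean over these weeks, the steps in time within each diet, and the change of the diet effect over time by a moderated F test. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01 between members, for lists with at least 3 tested members. It compares a list with the other miRNAs, so its calls are relative to the general shift, which exceeded 0.1 on the log2 scale in most comparisons: the median difference over all miRNAs was -0.11, 0.26 and -0.13 between the diets at weeks 6, 18 and 30, 0.58 and -0.16 in chow from week 0 to 6 and 6 to 18, and 0.49, -0.12 and -0.13 in high fat from week 0 to 6, 6 to 18 and 18 to 30. No list was called in any comparison with an estimated correlation. The 20 lists were smooth muscle, endothelium, macrophage and myeloid, lymphocyte, NF-kB induced, striated muscle, adipose, red blood cell, liver, neuron, epithelium, the miR-29 family, fibroblast, cholesterol and lipid regulators, the let-7 family, miR-17~92 and paralogs, the Dlk1-Dio3 cluster, disturbed flow, p53 and senescence, and GC-rich or ribosomal RNA derived entries. They hold 138 of the tested miRNAs.

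The comparisons, lists, most alternatives and the rule for named miRNAs were fixed before the data were examined. The rule takes the 10 higher and 10 lower miRNAs with the largest change among those past the threshold whose groups do not overlap, with the same sign at all 3 weeks for the mean diet effect. Where fewer than 10 pass, it adds the 10 with the smallest p, as values without a call. It also takes up to 4 members per list with the smallest p, up to 10 miRNAs of the diet by time test, and a fixed panel of 20 miRNAs in the diet comparisons. Of the panel, miR-33-5p was not tested because it was not detected on every array of any group. Where a miRNA was not well above background on any array of a group, the fold is given as a bound ("at least"): the mean of the brighter group against, per array of the dim group, the higher of the lowest detected signal and the miRNA's own.

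On simulated values with the real spreads and 609 miRNAs, for the week 6 diet effect, changes of 3 on the log2 scale were called for 18 of 20 miRNAs, changes of 2 for 11 of 20 and changes of 1 for 1 of 20, with 0 false calls among 549 unchanged miRNAs. Each miRNA was simulated independently, without the differences that real arrays share over many miRNAs. The 0 false calls therefore do not give the rate of false calls on the real arrays. The number of arrays limits the precision: the median standard error of a diet effect at 1 week was 0.61 on the log2 scale. Alternatives changed the background correction, the scaling, the summary over probes, the filter, the floor, the blocks for slide and replicate number, the groups in the fit, the spread model and the array weights, and left out each array in turn. Chosen after the data were seen were 4 more: leaving out 4 arrays that stood apart in signal or background, the week 18 diet by the array position in the description, averaging near-identical arrays, and the GC-rich list mean as a covariate. Figures were drawn with matplotlib 3.10.9.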

Results

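The study followed miRNAs in the lesion-bearing ascending aorta of double-knockout mice over 30 weeks on a high fat or a chow diet, with a week 0 group on chow. Between 316 and 742 mature miRNAs were detected per array. Fewest were detected on week 18 chow replicate 1 (316), week 18 high fat replicate 3 (328), week 6 high fat replicate 3 (345) and week 30 high fat replicate 1 (355). The SD of the negative controls was 22.3 on week 18 high fat replicate 3 and at most 2.53 on the other arrays. Over the miRNAs detected on every array, the SD of the log2 differences was 0.28 between week 6 chow replicates 1 and 2 and 0.18 between week 30 high fat replicates 2 and 3, the near-identical pairs within a group, against a median of 0.95 for pairs of one group on one slide. It was 0.19 between week 18 high fat replicate 3 and week 30 high fat replicate 2, which are of different groups. Week 18 high fat replicate 3 was left as it was when near-identical arrays were averaged. The arrays lay on 3 slides, each scanned in its own session. Slide 1 held weeks 0 and 6. Slide 2 held week 18 chow, week 30 chow and week 18 high fat replicates 1 and 2, and slide 3 held week 18 high fat replicate 3 and week 30 high fat. For 8 arrays the position on the slide differed between the description and the file, and for 2 of them, week 18 chow replicate 1 and week 18 high fat replicate 1, the description's position would switch the diet.

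**Figure D1:**
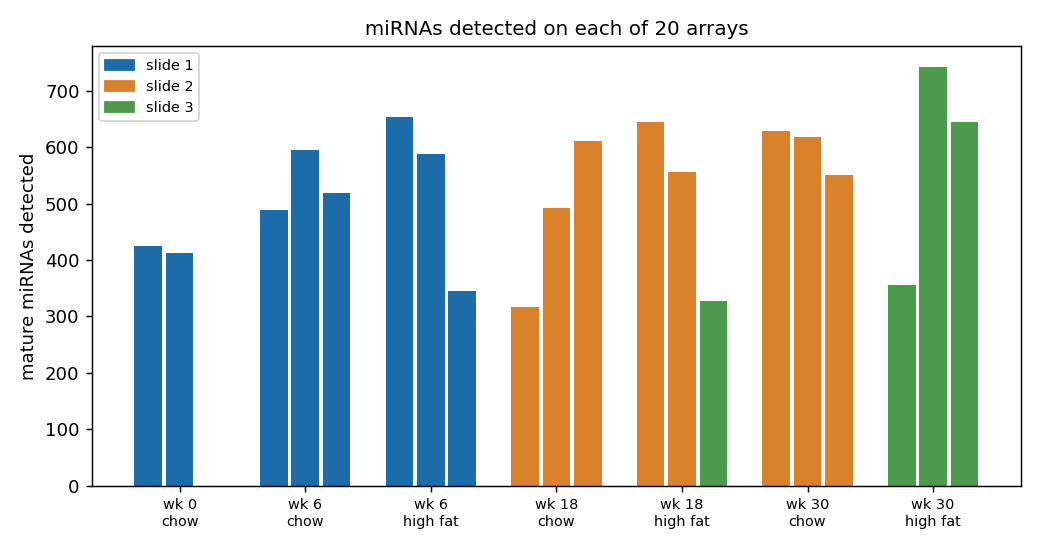
Number of mature miRNAs detected (y axis) on each of the 20 arrays, 1 bar per array, by group and coloured by slide. The bars run from 316 to 742, with low arrays in weeks 6, 18 and 30.

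The week 6 diet comparison asked whether high fat feeding had altered aortic miRNAs early. miR-128-3p, an abundant miRNA of brain and developing lymphocytes, was 3.70 lower on the log2 scale in high fat than in chow aortas (log2 difference -3.70, SE 0.52, adjusted p = 2.71e-04), at 5.79 ± 0.88 (SD, n = 3) against 9.49 ± 0.38 (SD, n = 3). miR-181b-5p differed by -2.67 (SE 0.41) and miR-181a-5p, which tunes T-cell receptor signalling, by -3.07 (SE 0.71, adjusted p = 0.0176). Of their family, named after the values were seen, miR-181d-5p passed (-1.67, SE 0.39) and miR-181c-5p did not (-1.69, SE 0.50, adjusted p = 0.106). The minor arm miR-181a-1-3p was at least 6.27-fold lower in high fat, where it was not well above background on any array (adjusted p = 6.76e-06). Of the further named miRNAs, miR-3097-5p fell by 2.68 on the log2 scale and miR-297c-5p fell by 2.34, with miR-670-5p, miR-3064-5p, miR-466p-5p and miR-539-5p between them, miR-466p-5p being at least 2.58-fold lower and not well above background in high fat. In all, 18 miRNAs were lower in high fat and 0 higher (limma, 609 tested, absolute log2 differences 1.49 to 3.70). Adjusted over the members of all 20 lists together, 6 passed. Both diets lay on slide 1, and a fit of that slide alone called 13 miRNAs, 12 of them among the 18.

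Probe-matched parts of these miRNAs lay, in build mm9, at chromosome 1 from 130098982 to 130099001 and chromosome 9 from 112021188 to 112021207 for miR-128-3p, whose genes Mir128-1 and Mir128-2 lie within the protein-coding genes R3hdm1 and Arpp21 in GRCm38.p6. For miR-181a-1-3p the position was chromosome 1, 139863090 to 139863106, and for miR-363-3p chromosome X, 50094923 to 50094940. Mir466p and Mir297c lie within Sfmbt2, Mir670 within the non-coding gene Mir670hg, Mir3097 within Rgs12 and Mir3064 within Ddx5.

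Of the lists at week 6, miR-17~92 and its paralogs, a proliferation-linked cluster family, was lower in high fat (13 tested members, median log2 difference -1.38, adjusted p = 6.67e-07; adjusted p = 0.446 with an estimated correlation). 2 members fell by the test over all miRNAs: miR-363-3p, at least 2.34-fold lower and not well above background in high fat, and miR-18a-5p, which fell by 1.85. The other 11 did not pass, among them miR-20b-5p (-2.24, adjusted p = 0.113) and miR-19a-3p (-1.89), and 8 of 13 passed when adjusted over the list alone, that is over these 13. The imprinted Dlk1-Dio3 cluster was higher as a list (15 members, median 0.60, 13 positive, adjusted p = 0.00877; adjusted p = 0.446 with an estimated correlation), although its member miR-539-5p fell and 14 did not pass. This call was lost without week 6 high fat replicate 3 (median 0.43, adjusted p = 0.0581), and 4 lists were called without week 6 high fat replicate 1. Among lists below the threshold, the striated muscle list had a median of 1.53, the red blood cell list of -1.22, the epithelium list of -0.56 (0 of 9 positive; list mean 6.26 ± 0.35 in chow and 5.33 ± 1.72 in high fat, SD, n = 3 each), the NF-kB list of 0.52, the fibroblast list of 0.36, the miR-29 family of 0.20 and the liver list of -0.26. The median was positive but the mean negative in the disturbed flow (0.43 and -0.39), endothelium (0.18 and -0.28) and neuron lists (0.44 and -0.46), and 1 member fell in each of the latter pair. No panel miRNA passed at week 6. miR-1a-3p and miR-133a-3p of striated muscle differed by 1.68 (SE 1.27) and 1.53 (SE 1.01), miR-143-3p and miR-145a-5p of smooth muscle by 0.13 (SE 0.54) and 0.18 (SE 0.34), and endothelial miR-126a-3p by 0.52 (SE 0.60). Of the immune panel members, miR-142a-3p differed by -0.82 (SE 1.02), miR-155-5p by 0.43 (SE 0.96), miR-146a-5p by 0.61 (SE 0.90), miR-223-3p by 0.51 (SE 0.55) and miR-150-5p by 0.67 (SE 1.12). The red cell miRNA miR-451a differed by -1.25 (SE 0.73). The count fell to 8 without week 6 chow replicate 1 and to 11 without week 6 high fat replicate 1, and rose to 29 without week 6 high fat replicate 2. It was 7 with near-identical arrays averaged, 8 with a floor lower by 1 on the log2 scale, 10 with the percentile over all miRNAs, 3 without scaling, 2 with normexp and 0 among the miRNAs detected on all 20 arrays.

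**Figure D2:**
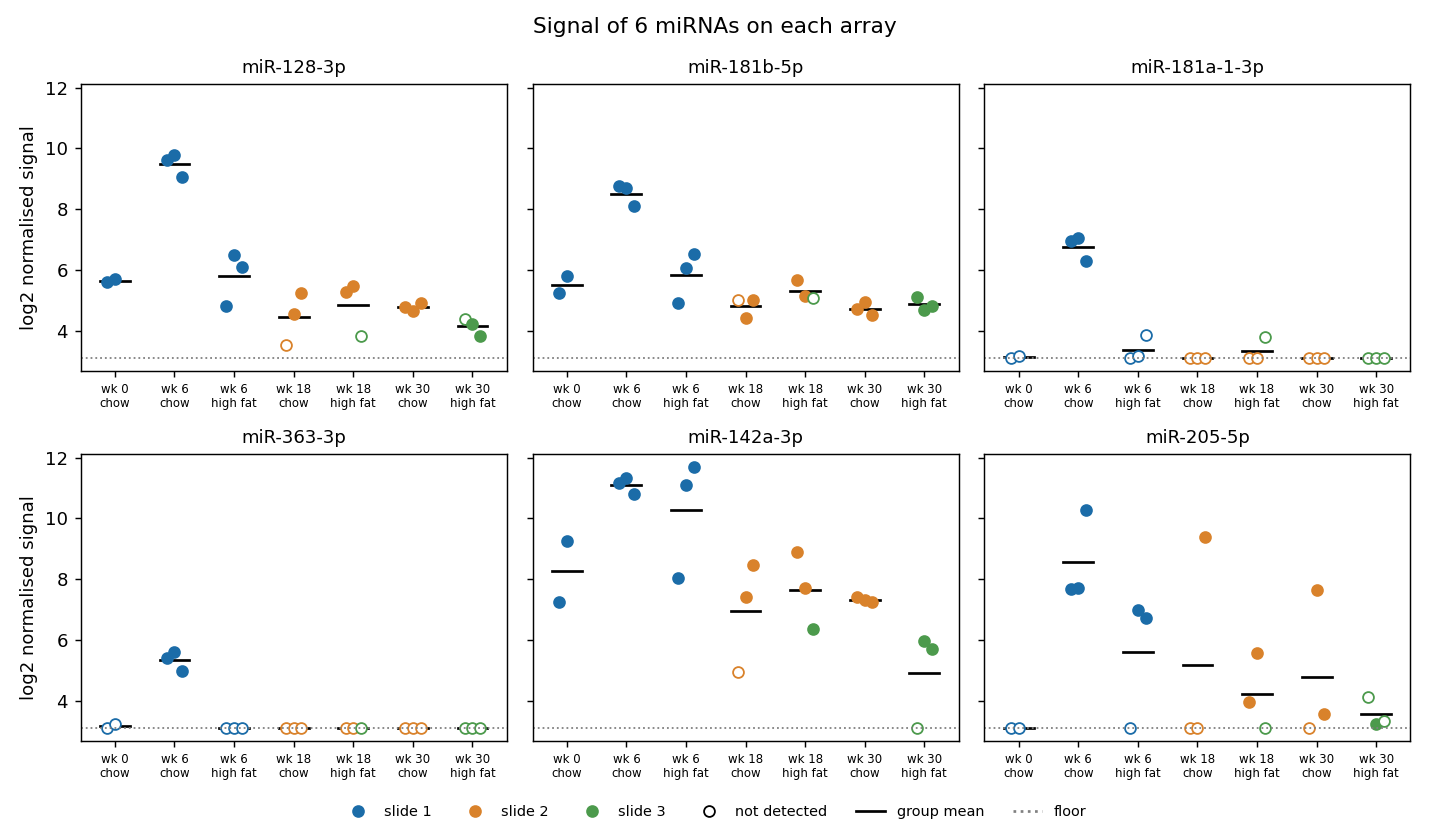
Log2 normalised signal (y axis) of 6 miRNAs on each array (points, coloured by slide, open where not detected) by group, with group means as black lines and the floor of 3.09 dotted. Week 6 chow stands above the other 6 groups in miR-128-3p (mean 9.49, other groups 4.14 to 5.79) and miR-181a-1-3p (mean 6.76, other groups 3.09 to 3.36).

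At week 18 no miRNA passed between the diets (0 of 609 with limma, smallest adjusted p = 0.954, 7 at an unadjusted p under 0.05). On the first principal component, the axis of largest variation between arrays (46.4% of the variance), 1 array of each diet lay apart. Week 18 chow replicate 1 and high fat replicate 1 lay at 30.9 and 27.7, and the other week 18 arrays at -12.7 to 5.56. The smallest p belonged to miR-6401 (1.28, SE 0.53), miR-382-5p (0.82, SE 0.36) and miR-455-3p (-1.85, SE 0.83). miR-128-3p, 3.70 lower at week 6, differed by 0.42 (SE 0.52) and miR-181b-5p by 0.49 (SE 0.41). No panel miRNA passed, and their differences ran from -0.72 (miR-210-3p, SE 0.41) to 1.09 (miR-122-5p, SE 0.67). The adipose list was lower in high fat (8 members, all negative, median -1.10, adjusted p = 1.14e-07; adjusted p = 0.0736 with an estimated correlation). Its members miR-455-3p, miR-193b-3p (-1.52, SE 0.71) and miR-378a-3p (-1.10, SE 0.58) did not pass singly. The epithelium (median -0.57, 0 of 9 positive), let-7 (median -0.29, 5 of 11 positive) and smooth muscle (median -0.15, 4 of 8 positive) lists were also lower relative to all miRNAs, whose median difference was 0.26, with no member past the threshold, adjusted p = 0.781 with an estimated correlation, and let-7 and smooth muscle medians of 0.74 and 0.88 without scaling. The adipose median was -1.31 both with the slide as a block and within slide 2, which gave 0 miRNAs, and it was 0.40 with the diet taken from the position in the description, where the smooth muscle median was 0.024. Week 18 high fat replicate 3 alone sets the block, so the block and slide 2 compare the same week 18 arrays. Their equal medians are therefore not separate support. Without week 18 chow replicate 3 the epithelium median was 1.06, without week 18 high fat replicate 1 the smooth muscle median was 0.040, and the number of lists called was 1 without this array or without week 18 high fat replicate 1, 2 without week 18 chow replicate 2, without week 18 high fat replicate 3 or with the slide as a block, and 8 without week 18 chow replicate 1.

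At week 30 no miRNA passed (0 of 609 with limma, smallest adjusted p = 0.167), with 114 at an unadjusted p under 0.05. miR-5135 differed by 2.0 (SE 0.45), miR-320-3p by 1.51 (SE 0.44) and miR-290a-5p by 1.40 (SE 0.40). miR-142a-3p, a miRNA of blood-forming cells, differed by -2.41 (SE 1.02) and miR-21a-5p, which is induced in injured vessels, by -1.74 (SE 0.78), miR-146a-5p by -1.56 (SE 0.90) and miR-145a-5p by 0.66 (SE 0.34). The let-7 family was lower as a list (11 members, all negative, median -0.76, adjusted p = 0.0400; adjusted p = 0.681 with an estimated correlation), a call lost without week 30 chow replicate 1 (adjusted p = 0.0712) or week 30 high fat replicate 3 (adjusted p = 0.0725). Below the threshold, the epithelium list had a median of -1.57 (adjusted p = 0.0525). Of the 20 lists, only the striated muscle and GC-rich lists had a higher mean in high fat than in chow. Without a call, the myeloid mean was 4.80 ± 0.16 (SD, n = 3) in high fat and 5.95 ± 0.32 (SD, n = 3) in chow. The p53 mean was 3.97 ± 0.10 (SD, n = 3) in high fat and 5.27 ± 0.80 (SD, n = 3) in chow. The mean of the GC-rich or ribosomal RNA derived list, a sign of RNA composition, was 9.23 ± 0.12 (SD, n = 3) in high fat and 8.71 ± 0.20 (SD, n = 3) in chow. The diets lay on different slides at this week. With the slide as a block, which rests on week 18 high fat replicate 3, 1 miRNA and 0 lists were called, and no slide held both diets of week 30. The count was 86 higher and 36 lower with only the 2 groups in the fit, 269 with array weights, 10 without the 4 arrays that stood apart and 5 without week 30 high fat replicate 1. The near-identical week 30 high fat replicates 2 and 3 had array weights of 11.3 and 4.12, against 0.23 for replicate 1. The pair also enters the spread of the fit with only the 2 groups. An understated spread from it cannot be told apart from diet in the first 2 of these counts.

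Averaged over weeks 6, 18 and 30, the diet effect was past the threshold for 1 of 609 miRNAs, miR-181a-1-3p (-1.06, SE 0.19, adjusted p = 0.0243), which did not have the same sign at all 3 weeks. Its mean rests largely on week 6, where it differed by -3.40, and its groups other than week 6 chow lay at or near the floor. Values at the floor add no spread to the SE. At week 6, miR-363-3p and miR-128-3p differed by -2.24 and -3.70, so their means too rest largely on that week. miR-363-3p (-0.75, SE 0.17), miR-128-3p (-1.31, SE 0.30) and miR-5135 (1.05, SE 0.26) did not pass. There were 105 at an unadjusted p under 0.05. The miR-17~92 (median -0.54), epithelium (median -1.0), let-7 (median -0.42) and cholesterol (median -0.39) lists were lower and the GC-rich list higher (median 0.46), all 5 with adjusted p = 0.737 with an estimated correlation. Of the panel, miR-34a-5p, a p53 target, had the smallest p (-0.72, SE 0.32). The count was 0 with the slide as a block, which left 1 list called. It was also 0 without any 1 of week 6 chow replicates 1 and 2, week 6 high fat replicate 2, week 18 chow replicates 2 and 3, week 18 high fat replicate 1, the week 30 chow replicates and week 30 high fat replicates 2 and 3, and 11 without week 18 high fat replicate 2, 7 without week 30 high fat replicate 1, 5 without week 18 chow replicate 1 and 2 without week 6 chow replicate 3. Lists called were 2 without week 6 high fat replicate 1, week 18 chow replicate 3 or week 18 high fat replicate 3. The cholesterol call was also lost without week 6 chow replicate 2 (adjusted p = 0.0562), week 6 high fat replicate 2 (adjusted p = 0.0601) or week 30 chow replicate 3 (adjusted p = 0.0672), and the GC-rich call without week 18 high fat replicate 1 (adjusted p = 0.0729).

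The diet effect changed over time for 6 of 609 miRNAs by limma's moderated F test, with 36 at an unadjusted p under 0.05. These were miR-181a-1-3p (adjusted p = 3.71e-04), miR-363-3p, miR-466p-5p, miR-181b-5p, miR-128-3p and miR-466a-5p. For miR-128-3p the diet effect was 4.13 higher at week 18 and 3.07 higher at week 30 than at week 6. For miR-181b-5p it was 3.16 and 2.82 higher. miR-181d-5p, next in order, did not pass (adjusted p = 0.0811). The count fell to 1 without week 6 chow replicate 1 or without week 6 chow replicate 2, rose to 12 without week 30 high fat replicate 1 and was 1 with near-identical arrays averaged.

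**Figure D3:**
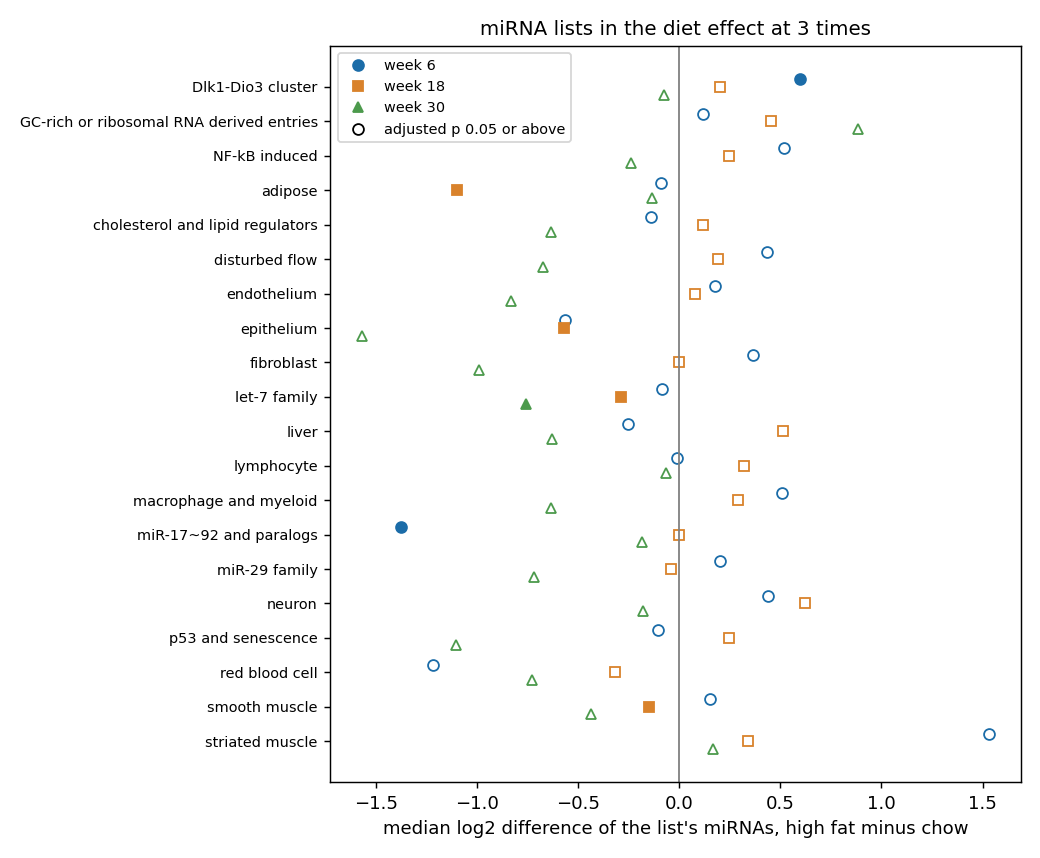
Median log2 difference, high fat minus chow (x axis), of each of the 20 miRNA lists (y axis) at weeks 6, 18 and 30, filled where the list passed an adjusted p of 0.05 with the preset correlation. The miR-17~92 median is -1.38 at week 6 and the adipose median -1.10 at week 18.

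On chow, week 6 aortas were compared with week 0 aortas. Among the increases were miR-205-5p, an epithelial miRNA (at least 27-fold, adjusted p = 0.0307), miR-376c-3p of the Dlk1-Dio3 cluster (at least 25.7-fold), miR-3063-3p (at least 23-fold) and miR-7212-3p (at least 20.1-fold), none of which was well above background at week 0. The muscle miRNA miR-206-3p rose by 5.01 (SE 1.34), miR-669k-5p by 4.35 (SE 1.13), miR-6348 by 4.26 (SE 1.35), miR-1943-3p by 4.15 (SE 1.12) and miR-672-5p by 4.02 (SE 1.33), and miR-7235-3p was at least 12.9-fold higher. miR-28c, within Samd12, fell by 1.10 (SE 0.36), with a difference of 0.16 under normexp. In all, 123 were higher and 1 lower of 609 with limma, and 63 of these were not well above background at week 0. Adjusted over the members of all 20 lists together, 16 passed. The median of all miRNAs differed by 0.58, and the split was 32 higher and 21 lower after quantile normalization and 28 higher and 60 lower with the percentile over all miRNAs. The miR-17~92 list was higher (median 1.59, 6 of 13 rose, 7 did not pass), and the smooth muscle (median -0.62) and adipose (median -0.68) lists were lower with no member past the threshold. All 3 had adjusted p = 0.634 with an estimated correlation, and without week 0 chow replicate 1 the adipose (adjusted p = 0.153) and miR-17~92 (adjusted p = 0.0823) calls were lost, the latter also within slide 1 (adjusted p = 0.0595). The epithelium list, below the threshold (adjusted p = 0.439), had a median of 2.82, with 8 of 9 positive and 1 past the threshold. The week 0 group held 2 arrays, and the count was 9 without week 0 chow replicate 1, 38 without week 0 chow replicate 2, 17 without week 6 chow replicate 1, 41 without week 6 chow replicate 2, 11 with near-identical arrays averaged and 1 without scaling.

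From week 6 to week 18 on chow, 100 miRNAs fell and 0 rose (limma, 609 tested), and 20 passed when adjusted over the members of all 20 lists together. miR-128-3p fell by 5.06 (SE 0.52, adjusted p = 7.20e-06), to 4.43 ± 0.87 (SD, n = 3). The blood-cell miRNAs miR-142a-3p and miR-142a-5p fell by 4.15 (SE 1.02) and 3.86 (SE 0.93), miR-181b-5p by 3.70 (SE 0.41), miR-181a-5p by 3.38 (SE 0.71) and miR-466j by 3.20 (SE 1.02). miR-130b-3p was at least 7.51-fold and miR-181a-1-3p at least 5.68-fold lower, both not well above background at week 18. The miR-17~92 list was lower (median -2.11, 11 of 13 members fell and 2 did not pass, adjusted p = 3.61e-07; adjusted p = 0.545 with an estimated correlation), with miR-20b-5p at -3.80 (SE 0.68) and miR-19a-3p at -3.20 (SE 0.63). Below the threshold lay the lymphocyte list (median -1.34, 2 of 6 fell) and the myeloid list (median -1.0, 2 of 5 fell). The epithelium (median -1.33, 0 of 9 positive) and red blood cell lists (median -1.43, 0 of 4 positive) lay there too, with no member of either past the threshold. The weeks lay on different slides with no slide in common, so slide and time cannot be told apart. The count was 48 without week 6 chow replicate 1, 58 without week 6 chow replicate 2, 54 without week 18 chow replicate 1, 1.5e+02 without week 18 chow replicate 2, 30 of them higher, and 14 with normexp.

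From week 18 to week 30 on chow, 0 of 609 miRNAs passed with limma (6 at an unadjusted p under 0.05, smallest adjusted p = 0.996) and no list was called, against 10 lists without week 18 chow replicate 1, 2 without week 18 chow replicate 3 or week 30 chow replicate 2 and 1 without week 30 chow replicate 3. miR-297a-3p (1.25, SE 0.54), miR-669d-3p (1.30, SE 0.58) and miR-669b-3p (1.27, SE 0.58) had the smallest p. Slide 2 alone also gave 0.

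On the high fat diet, 0 of 609 miRNAs passed with limma in any step. From week 0 to week 6, 45 had an unadjusted p under 0.05, among them miR-206-3p (3.58, SE 1.34), miR-376c-3p (3.94, SE 1.47) and miR-31-5p (-1.33, SE 0.53). The striated muscle list was higher (5 members, all positive, median 2.51, adjusted p = 0.00784; adjusted p = 0.365 with an estimated correlation), a call lost without week 0 chow replicate 1 (median 1.05, adjusted p = 0.354) or week 6 high fat replicate 3 (adjusted p = 0.0762). Relative to all miRNAs, whose median difference was 0.49, the smooth muscle (median -0.50) and adipose (median -0.70) lists were lower (adjusted p = 0.206 with an estimated correlation for both), as were the let-7 (median -0.20; adjusted p = 0.365 with an estimated correlation) and red blood cell lists (median -0.60; adjusted p = 0.303 with an estimated correlation). The cholesterol list was also lower by the test, although its median was 0, its mean 0.036, and 5 of 11 members were positive and 1 was at the floor in both groups (adjusted p = 0.501 with an estimated correlation). Without week 0 chow replicate 1 the adipose (adjusted p = 0.0697), red blood cell (adjusted p = 0.354) and cholesterol (adjusted p = 0.187) calls were lost, and without week 0 chow replicate 2 the let-7 call (adjusted p = 0.0915). Without week 6 high fat replicate 1 the let-7 (median 0.14, adjusted p = 0.392), cholesterol (median 0.40, adjusted p = 0.686) and red blood cell (adjusted p = 0.105) calls were lost, and without week 6 high fat replicate 3 the red blood cell call (adjusted p = 0.0663). The cholesterol call was also lost within slide 1 (adjusted p = 0.0782). Without the 4 arrays that stood apart, 94 miRNAs passed in this step.

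From week 6 to week 18 on high fat, 61 miRNAs had an unadjusted p under 0.05. miR-7036a-5p (3.54, SE 1.05), miR-142a-5p (-3.04, SE 0.93) and miR-6769b-5p (3.03, SE 0.94) led them. The macrophage and myeloid (median -1.55), miR-17~92 (median -0.73), let-7 (median -0.61), epithelium (median -1.07) and NF-kB (median -1.02) lists were lower, with adjusted p = 0.628 with an estimated correlation for each, no member past the threshold over all miRNAs and a let-7 median of 0.18 without scaling. None of the 5 was called without week 6 high fat replicate 3 or without week 18 high fat replicate 3. The epithelium call was also lost without week 6 high fat replicate 2 (adjusted p = 0.161) or week 18 high fat replicate 1 (adjusted p = 0.0651), and the NF-kB call without week 18 high fat replicate 2 (adjusted p = 0.0848). Slide and time cannot be told apart in this step. From week 18 to week 30 on high fat, 18 had an unadjusted p under 0.05, among them miR-204-5p (-1.03, SE 0.35), miR-10b-5p (-1.75, SE 0.61), miR-142a-3p (-2.73, SE 1.02) and miR-146a-5p (-2.17, SE 0.90). Week 18 high fat replicate 3 was closer to week 30 high fat replicates 2 and 3 than to its own group, which limits this step. The myeloid (median -1.12), let-7 (median -0.54), endothelium (median -0.77) and p53 (median -0.86) lists were lower (adjusted p = 0.452 with an estimated correlation), and the adipose list was higher (median 1.00; adjusted p = 0.464 with an estimated correlation). No list was called without week 18 high fat replicate 1 and 11 were without week 18 high fat replicate 3, and 2 miRNAs passed without week 30 high fat replicate 1. The let-7 (adjusted p = 0.204) and p53 (adjusted p = 0.268) calls were lost without week 18 high fat replicate 2, the adipose call without week 30 high fat replicate 1 (adjusted p = 0.701), and the p53 call without week 30 high fat replicate 2 (adjusted p = 0.0727) or 3 (adjusted p = 0.0747). By the position in the description the adipose median was -0.13, and the adipose, myeloid (adjusted p = 0.134), endothelium (adjusted p = 0.0699) and p53 (adjusted p = 0.0824) calls were lost. With the slide as a block, 1 miRNA and 0 lists passed, with myeloid and p53 medians of 0.068 and 0.026, and slide 3 alone, with 1 array of week 18, gave 13 miRNAs.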

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

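The tests of leukocytes in general and of near-identical arrays were chosen after the results were seen. The diet effect differed between the weeks for 6 miRNAs by the test of that difference: adjusted p was 3.71e-04 for miR-181a-1-3p, 0.00860 for miR-363-3p and for miR-466p-5p, 0.00988 for miR-181b-5p, 0.0114 for miR-128-3p and 0.0214 for miR-466a-5p. When the diets were reassigned within weeks in 100 regroupings, the real one included, 13 gave at least the 6 calls observed and the highest of the others gave 2.2e+02, so chance is not excluded for that count. Only 1 regrouping gave many times the real count, and the next highest gave 18. A structure of the samples other than diet may underlie that regrouping, which was not tested. All 6 were high on the 3 week 6 chow arrays and low elsewhere.

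For the week 6 difference between diets, a larger share of leukocytes in general was set to need a drop of 1 or more, which was not seen. The 7 leukocyte miRNAs, all members of the fixed lists, had a median of 0.51 (high fat minus chow, SD 0.67 between members). The most abundant, miR-142a-3p and miR-142a-5p (11.10 and 8.71 in week 6 chow), differed by -0.82 and -0.63. The SE of a member's difference was 0.55 to 1.12, and the test was chosen after the results were seen. A larger share of leukocytes is therefore not excluded at week 6. For the steps in chow it stays open: the median was -1.36 from week 6 to week 18 (SD 1.47, 7 negative, 2 called), where slide and time cannot be told apart, and -0.33 from week 0 to week 6 (SD 1.56, 4 negative), with miR-142a-3p at 2.85. Immature lymphoid tissue such as thymus, which lies beside the ascending aorta, stays open as a candidate source, as does diet itself, which was not tested apart from it. Its list of 10 marker miRNAs was written before their week 6 values were seen, and the 7 tested, of which 4 were detected on all 20 arrays and so are present in every aorta sample, had a median of -0.92 (6 negative, 0 called), between the drop of 1 set as needed and the 0.5 set as too small, with -1.81 from week 6 to week 18 in chow (7 negative, 1 called), where slide and time cannot be told apart, and 0.82 from week 0 to week 6 (SD 0.69, 1 negative, 0 called), and the most abundant of them, miR-15b-5p and miR-16-5p, were at 11.21 and 11.01 in week 6 chow and 9.69 and 10.20 in week 6 high fat. With the 2 near-identical week 6 chow arrays averaged, 7 of the 18 miRNAs passed. For these 7, an understated spread from that pair is argued against as the whole source of the call. Averaging does not address values at the floor, which add no spread. Of the 7, miR-181a-1-3p, miR-363-3p and miR-466p-5p were not well above background in high fat. For the other 11, an understated spread from the pair cannot be told apart from the loss of an array. Their median standard error rose from 0.47 to 0.56 while their median absolute difference went from 2.33 to 2.25.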

How the results depend on the processing

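The alternatives of leaving out 4 arrays, of the position in the description, of near-identical arrays and of the GC-rich covariate were chosen after the data were seen. Among the named miRNA results called, 613 of 812 alternatives kept direction and call, 198 lost the call and 1 reversed, and of 4071 alternatives for named miRNA results not called, 82 were called. For the 32 list results called, 489 of 671 alternatives kept direction and call, 179 lost the call and 3 reversed. These totals include the deposited value table, whose values equal those of the main fit, so 1 alternative per result could only stay the same. For miRNAs, the slide as a random block, at a correlation within slides of 0.00089, nearly repeated the main fit. miR-128-3p at week 6 kept its call in all 26 (log2 difference -4.05 to -2.67, adjusted p 2.15e-05 to 0.0200). The others of the 10 week 6 miRNAs with the largest change lost the call in 1 (miR-181a-1-3p) to 15 (miR-297c-5p) of 26. The reversals, for lists by the direction of the test, were miR-28c in chow from week 0 to 6 with normexp (0.16, adjusted p = 0.819), the epithelium list at week 18 without week 18 chow replicate 3 (1.06, adjusted p = 0.935), and at week 18 by position label the adipose list (0.40) and the smooth muscle list (0.024). The median of a called list changed sign in 8 more alternatives, all with the call lost: without scaling in let-7 (0.74) and smooth muscle (0.88) at week 18 and let-7 in high fat 18 v 6 (0.18), with the slide as a block in the myeloid (0.068) and p53 lists (0.026) in high fat 30 v 18, by position label in the adipose list there (-0.13), without week 6 high fat replicate 1 in let-7 in high fat 6 v 0 (0.14), and without week 18 high fat replicate 1 in smooth muscle at week 18 (0.040). The cholesterol median in high fat 6 v 0, which was 0, reached 0.40 without week 6 high fat replicate 1. Over the arrays left out in turn, the epithelium list's median at week 18 ran from -1.33 to 1.06. Counts of calls that moved by over 1.5 times follow, and the cause was not tested except that fewer miRNAs or arrays enter some fits. Normexp background correction gave miRNA counts of 2 for diet at week 6, 0 for the mean diet effect, 39 for chow 6 v 0, 14 for chow 18 v 6, 3 for high fat 18 v 6, 0 for diet by time. Quantile normalization gave miRNA counts of 0 for the mean diet effect, 53 for chow 6 v 0, 46 for chow 18 v 6, 1 for diet by time, and list counts of 2 for diet at week 18, 1 for chow 6 v 0, 3 for high fat 6 v 0, 3 for high fat 30 v 18. 75th percentile over all miRNAs gave miRNA counts of 10 for diet at week 6, 0 for the mean diet effect, 14 for chow 18 v 6, 0 for diet by time, and list counts of 0 for diet at week 30, 3 for the mean diet effect, 2 for chow 18 v 6, 3 for high fat 18 v 6, 2 for high fat 30 v 18. No scaling between arrays gave miRNA counts of 3 for diet at week 6, 0 for the mean diet effect, 1 for chow 6 v 0, 5 for chow 18 v 6, 0 for diet by time, and list counts of 1 for diet at week 6, 3 for the mean diet effect, 2 for chow 18 v 6, 4 for chow 30 v 18, 9 for high fat 30 v 18. Scanner software's total signal per miRNA gave list counts of 2 for diet at week 18, 3 for diet at week 30, 1 for chow 30 v 18, 3 for high fat 18 v 6. Brightest probe gave miRNA counts of 2 for diet at week 30, 7 for the mean diet effect, 13 for diet by time, and list counts of 0 for diet at week 30. No filter on dim miRNAs gave miRNA counts of 9 for diet at week 30, 8 for the mean diet effect, 60 for chow 6 v 0, 3 for high fat 30 v 18, 13 for diet by time. Only miRNAs detected on all 20 arrays gave miRNA counts of 0 for diet at week 6, 0 for the mean diet effect, 0 for chow 6 v 0, 1 for chow 18 v 6, 0 for diet by time. A floor lower by 1 on the log2 scale gave miRNA counts of 8 for diet at week 6, 0 for the mean diet effect. Slide as a fixed block gave miRNA counts of 1 for diet at week 30, 0 for the mean diet effect, 1 for high fat 30 v 18, and list counts of 2 for diet at week 18, 0 for diet at week 30, 1 for the mean diet effect, 0 for high fat 30 v 18. Only arrays of slide 3 gave miRNA counts of 13 for high fat 30 v 18, and list counts of 0 for high fat 30 v 18. Only the groups of the comparison gave miRNA counts of 1.2e+02 (86 higher and 36 lower) for diet at week 30, 0 for the mean diet effect, 235 for chow 6 v 0. Intensity trend and robust spread gave miRNA counts of 6 for the mean diet effect. Array weights gave miRNA counts of 19 for diet at week 18, 269 for diet at week 30, 189 for the mean diet effect, 268 for chow 6 v 0, 360 for chow 18 v 6, 1 for chow 30 v 18, 18 for high fat 30 v 18, 109 for diet by time. With an estimated correlation, 0 lists passed in the 9 comparisons that had any. Without the 4 arrays that stand apart gave miRNA counts of 10 for diet at week 30, 7 for the mean diet effect, 202 for chow 6 v 0, 94 for high fat 6 v 0, 1 for high fat 30 v 18, and list counts of 5 for diet at week 6, 3 for chow 18 v 6, 11 for chow 30 v 18, 0 for high fat 18 v 6, 8 for high fat 30 v 18. Week 18 diet by the position label gave miRNA counts of 4 for the mean diet effect, 1 for high fat 18 v 6, and list counts of 3 for the mean diet effect, 4 for chow 30 v 18, 3 for high fat 30 v 18. Near-identical arrays averaged gave miRNA counts of 7 for diet at week 6, 0 for the mean diet effect, 11 for chow 6 v 0, 44 for chow 18 v 6, 1 for diet by time, and list counts of 0 for diet at week 30. GC-rich list mean as a covariate gave list counts of 1 for diet at week 18, 3 for the mean diet effect, 4 for chow 18 v 6, 3 for high fat 6 v 0, 3 for high fat 30 v 18. Leaving out each array in turn gave miRNA counts of 48 to 1.5e+02 for chow 18 v 6, 0 to 0 for chow 30 v 18, 9 to 86 for chow 6 v 0, 1 to 12 for diet by time, 0 to 0 for diet at week 18, 0 to 5 for diet at week 30, 8 to 29 for diet at week 6, 0 to 0 for high fat 18 v 6, 0 to 2 for high fat 30 v 18, 0 to 0 for high fat 6 v 0, 0 to 11 for the mean diet effect. List counts ran from 1 to 4 for chow 18 v 6, 0 to 10 for chow 30 v 18, 2 to 4 for chow 6 v 0, 1 to 8 for diet at week 18, 0 to 3 for diet at week 30, 2 to 4 for diet at week 6, 0 to 7 for high fat 18 v 6, 0 to 11 for high fat 30 v 18, 5 to 7 for high fat 6 v 0, 2 to 6 for the mean diet effect. The replicate numbers gave no clear pairing of the samples: same-numbered arrays correlated above 0.1 in 24 of 57 pairs and 9 of 20 arrays correlated best with their own number. These correlations are of deviations from the group means. Their mean was 0.088 for the same number and -0.038 for other numbers, so some shared structure is not excluded. The replicate block gave 18 at week 6, 115 for chow 18 v 6, a count within 1.5 times for chow 6 v 0, 1 for the mean diet effect, 6 for diet by time and 0 for the rest, with list counts of 2, 4, 1, 5, 3, 1, 0, 7, 5 and 5 in the order of the comparisons. The correlation within slides was 0.00089, and the slide as a random block changed no count of miRNAs. Only week 18 high fat lay on more than 1 slide, so the group means take up most of any slide difference. This correlation therefore cannot show that the slides do not differ. List tests with the slide as a random block were not run, since camera takes no random block, and no fixed block or single slide could be fitted for week 18 against week 6. Array weights ranged from 0.12 to 11.3, from a fit that did not fully converge. The highest was that of week 30 high fat replicate 2, which is near-identical to week 30 high fat replicate 3. Of the 4 arrays that stood apart, 3 had the 3 lowest scaling factors, while week 18 high fat replicate 3 had the highest scaling factor and a negative-control SD of 22.3. Whether low signal limits detection on those 3 was not tested.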

Other observations

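The tests of slide 3 and of the GC-rich list were chosen after the results were seen. The epithelial miRNA mmu-miR-205-5p ranged from the floor of 3.09 to 9.39 among the week 18 chow arrays and from 3.09 to 7.64 among the week 30 chow arrays, and it was detected on 1 and 2 of the 3 arrays. In week 6 chow it was detected on all 3, at 7.69 to 10.26.

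The 18 miRNAs lower in high fat at week 6 were all among the 100 that fell in chow from week 6 to week 18 (2.96 for independent lists) and all among the 123 that rose in chow from week 0 to week 6 (3.64 for independent lists). The 3 comparisons share the week 6 chow arrays. These could not be split with at least 2 arrays in each part, so part of the overlap can come from sharing them. Simulated unchanged groups give almost no calls, so their highest overlap of 0 in 100 simulations is no reference. The log2 differences of the first pair of comparisons had a covariance of 0.93 against a mean of 0.25 in the simulations, and those of the second pair -0.86 against a mean of -0.26. The simulations drew each miRNA independently, without the differences that real arrays share over many miRNAs. The covariances therefore do not decide how much of the overlap comes from the shared arrays.

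Week 18 high fat replicate 3 was closer to week 30 high fat replicates 2 and 3 than to its own group. The SD of the log2 differences over the miRNAs detected on all 20 arrays was 0.19 and 0.33 to these, and at least 1.02 to the arrays of its group. A wrong label or 1 RNA hybridised more than once could give this, and so could the shared slide, for which the farthest pair of slide 3 arrays had an SD of 1.27 against a median of 0.95 for pairs of one group on one slide. All pairs above that median include week 30 high fat replicate 1, so neither explanation is excluded, and slide and label cannot be told apart.

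Whether the mean of the GC-rich list follows low signal was examined with 2 measures, the scaling factor and the number of detected miRNAs. Over 20 arrays, Spearman's rho with the scaling factor was -0.0030 (permutation p = 0.992, adjusted p = 0.992 over the 2 measures) and Pearson's r -0.21 (permutation p = 0.385, adjusted p = 0.771). Without the 2 arrays farthest from the median, r was 0.15 and rho 0.26. Within slides 1 and 2, of 8 arrays each, r was -0.49 and -0.41. With the number of detected miRNAs, rho was 0.10 over 20 arrays and 0.37 without the 2 arrays farthest by that measure. Within slides 1 and 2 it was 0 and 0.26. These values leave low signal open as an explanation.

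Other splits of the same arrays were counted for each comparison of 3 against 3, which has 10 splits, too few for a share under 0.05. The filter on detection was set anew for each split and regrouping. A miRNA tested only because every array of 1 real group detected it can thus drop out of the others. The counts of the other splits can be low in part for that reason. For miRNAs, the real split gave 18 at week 6 (highest other 0, 1 split as large), 100 in chow from week 6 to 18 (highest other 6, 1 as large), and 0 at weeks 18 and 30, in chow from week 18 to 30 and in high fat from week 6 to 18 and 18 to 30 (10 as large in each). The highest others of these were 1.9e+02, 0, 0, 72 and 5. The first of these splits, the only one at week 18 with any call, set week 18 chow replicate 1 and week 18 high fat replicates 1 and 3 against the others and follows no single slide. This split and the one with 72 calls in high fat each set the 3 arrays highest on the first principal component against the 3 lowest. That axis of largest variation between arrays held 46.4% of the variance. In the week 18 split the 2 sides ran from 5.56 to 30.9 and from -12.7 to 0.34. In the high fat split they ran from 0.14 to 27.7 and from -26.4 to -0.11. Both splits thus follow this axis rather than the groups, and its source was not tested. The real split in chow from week 6 to 18 also ran along it. Its arrays lay at -26.1 to -16.1 at week 6 and -12.7 to 30.9 at week 18. Other high fat splits from week 6 to 18, with 71, 13, 11 and 1 calls, did not set the highest arrays against the lowest. The axis therefore does not account for every high count. For lists, as many as the real count came from 9 splits at week 6 (2 real, highest other 14), 5 at week 18 (4 and 9), 7 at week 30 (1 and 6), 6 in chow from week 6 to 18 (1 and 5), 10 in chow from week 18 to 30 (0 and 6), 5 in high fat from week 6 to 18 (5 and 7) and 4 in high fat from week 18 to 30 (5 and 9). For the mean diet effect, 11 of 100 regroupings gave at least the 1 call (highest other 1.3e+02) and 28 gave at least the 5 lists (highest other 12), so chance is not excluded.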
